A study of Mus musculus with 33 samples.

How the data were processed

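The samples were C2C12 cells, a mouse myoblast line that grows as single cells in rich serum and fuses into multinucleated myotubes when serum is withdrawn. Growing myoblasts were kept in 10% fetal bovine serum. Myotubes were collected after 96 h (4 days) in 2% horse serum. Proteins bound to DNA were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which chromatin fragments held by an antibody are sequenced and stretches with many fragments are listed as peaks. ING1 was pulled down through a Flag tag in a stable line that expressed the tagged protein, and the other factors through antibodies against the proteins themselves, per the labels' protocols.

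The labels describe 33 samples, of which 17 were ChIP samples of a named factor, 10 were inputs and 6 were RNA-seq samples of cells given small interfering RNAs that were non-specific, against MLL3, or against MLL3 and MLL4. Groups and replicate numbers came from the sample titles. The input and RNA-seq samples were not analysed here. For Sin3A the series design text speaks of growing myoblasts while the sample labels say myotubes, and the sample labels were followed. The MLL1 samples carry Menin in their source label, MLL in their title and MLL1 as their antibody, and the title and antibody were followed. Nothing in the labels says that replicates came from separate cultures, so p-values across replicates measure only the spread between these samples, which may be technical.

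The deposited values were peak boundaries, that is the chromosome, the left and the right end of each peak in base pairs, per the file headers, and no height, fold or significance accompanied a peak. There were 14 lists of single replicates, pooled lists for 6 groups made by the authors, and 1 list each for LSD1 in myoblasts, LSD1 in myotubes and MLL3 in myoblasts. Bowtie 0.12.9, SAMtools 0.1.19 and bedtools 2.17.0 and the mouse builds mm9 and NCBIM37 are named per the submitters' processing notes. The role of each tool, the peak caller, its threshold and the way replicates were pooled are not given in the sources used here. Coordinates below are mm9. Left ends were read as counted from 0, and the starts printed here are counted from 1. Because the lists hold no read counts, the sequencing depth behind each list is unknown, and the length of a list depends on that depth as well as on binding.

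Peaks on the mitochondrial genome were left out of all overlaps, which used chromosomes 1 to 19 and X. Peaks were called shared when they overlapped by at least 1 bp. The overlap of a shorter with a longer list was compared with 1000 random circular shifts of the shorter list within each chromosome, by at least 1 Mb, which keep the spacing and widths of its peaks. The p-value was one-sided in the observed direction, and 0.0010 was the smallest that these shifts could give. Adjustment for multiple testing followed Benjamini and Hochberg over the 15 pairs of myoblast lists, over the 3 pairs of myotube lists and over the 10 pairs of replicate lists. Per-replicate values of ING1 were compared between 2 myoblast and 3 myotube lists by exact permutation tests over all 10 arrangements, two-sided, with 0.2 as the smallest p. Classes of peaks were compared by the odds ratio, by the odds ratio within 10 classes of peak width, and by the number of the 20 chromosomes on which the direction held, with an exact two-sided binomial test. Peaks are not independent replicates, so such tests describe these lists. Intervals on shares are exact binomial 95% intervals and cover counting error only.

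The overlaps between states and between factors, the circular shifts, the overlap rule, the test of ING1 peaks per list and the rule for naming regions were fixed before the data were examined. The classes of kept and other peaks, the shares of other factors in the ING1 replicate lists, the pairs of ING1 replicate lists within and between states, the shares per chromosome and the MLL3 coverage by distance were chosen afterwards. Promoter classes, the position of peaks relative to genes and tests of gene lists had also been planned. They need a gene annotation of build mm9, which was not used here, so regions are given by their coordinates. By the fallback rule, the named regions of each pooled or single list were its 5 widest peaks that overlapped a peak in every replicate list of the group, 45 in all, and for the 3 lists without replicates the 5 widest. A RefSeq gene table of assembly GRCm38.p6 served only to count protein-coding genes per chromosome, 20151 after olfactory, vomeronasal and trace amine receptor genes were left out.

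Alternatives fixed in advance were the wider 50% of each list, an overlap of 50% of the shorter peak, peaks within 500 bp, unions of the replicate lists, omission of each replicate, lists of equal length and a replicate block for ING1. Alternatives added later were local shifts by 20 to 200 kb, which keep peaks in the same part of the chromosome, pooled peaks present in every replicate list, mitochondrial peaks kept, and peak classes matched on width. Alternatives used 200 shifts. Keeping the mitochondrial peaks moved no pairwise share by more than 0.0903 percentage points. Overlap counting was checked against bedtools 2.31.1 in 9 cases, all equal. On simulated lists with planted overlaps the recovered share differed from the planted one by at most 0.728 percentage points, and 5 of 100 unrelated simulated pairs gave a p under 0.05. Because the p follows the observed direction, more than 5 in 100 such pairs would pass on average. The simulated peaks lay at random positions without the clustering of real lists, so this check says little about false positives in the real lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.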

Results

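Binding of 7 chromatin proteins was mapped in C2C12 cells. In growing myoblasts the lists covered ING1, a reader of trimethylated H3K4 that belongs to Sin3 histone deacetylase complexes; Menin, a subunit of MLL1 complexes; MLL1 and MLL3, which methylate H3K4; Wdr5, a core subunit shared by MLL complexes; and LSD1, which removes methyl groups from H3K4. In myotubes they covered ING1, LSD1 and Sin3A, the scaffold of the Sin3 deacetylase complex. Replicates numbered 2 for ING1 in myoblasts, Menin, MLL1 and Sin3A, and 3 for ING1 in myotubes and Wdr5. LSD1 and MLL3 had a single list per state and therefore no replicate check. The series title names H3K4 mono-methylation and the partitioning of chromatin readers as its subject.

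The 9 lists differed in length and in the width of their peaks. MLL3 had 218204 nuclear peaks covering 169.7 Mb, Menin 70050 peaks covering 69.1 Mb and Wdr5 59248 peaks covering 46.0 Mb. ING1 had 8196 peaks in myoblasts and 9698 in myotubes, MLL1 had 8892 and Sin3A 14088. LSD1 had 4442 peaks in myoblasts and 16504 in myotubes. Median widths ran from 392 bp for LSD1 in myoblasts to 723.5 bp for ING1 in myoblasts, and peaks over 5 kb were found mainly for Menin (682 peaks) and MLL3 (344 peaks). Every list was over-represented on chromosome 15, where its share of peaks was 1.62 to 2.46 times the share of protein-coding genes, and under-represented on chromosome 7, at 0.301 to 0.711 times. Chromosome X was low in 8 lists, at 0.109 to 0.399 times, and held 0.931 times its gene share in the MLL3 list. Relative to the length between the first and last peak of each chromosome, the ratios were 1.58 to 2.40 on chromosome 15 and 0.0823 to 0.704 on X. On chromosome 7 they were 0.414 to 0.980, so the deficit there was small for ING1 in myotubes (0.980) and myoblasts (0.920).

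**Figure D1:**
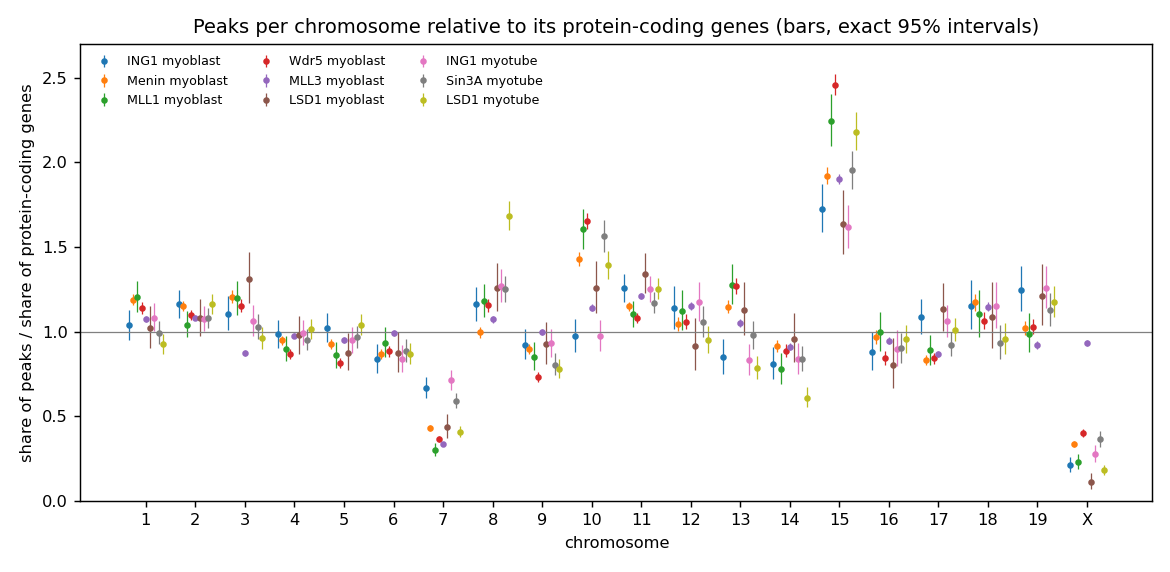
Share of the peaks of each list on each chromosome (x axis) divided by that chromosome's share of protein-coding genes (y axis); points are the 9 lists and bars exact binomial 95% intervals. All 9 lists lie above 1 on chromosome 15 and below 1 on chromosomes 7 and X.

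Replicate lists of a factor overlapped one another far more than shifted lists did, yet they differed widely in length. Sin3A replicate 2 had 430 peaks, of which 97.9% lay in the 9390 peaks of replicate 1. MLL1 replicate 2 had 466 peaks, of which 83.9% lay in replicate 1. For ING1 in myoblasts 79.4% of the 428 peaks of replicate 1 lay among the 5528 of replicate 2, and for Menin 70.2% of the 15865 peaks of replicate 2 lay in replicate 1. The 3 Wdr5 pairs shared 61.0% to 72.2% of the shorter list and the 3 pairs of ING1 in myotubes 62.0% to 69.0%. All 10 pairs exceeded every circular shift (permutation by shifts, adjusted p = 0.0010 for each). Of the pooled peaks, 36.6% for Sin3A, 41.6% for ING1 in myoblasts, 59.5% for MLL1, 67.3% for ING1 in myotubes, 71.1% for Menin and 83.2% for Wdr5 met no peak of any replicate list, and those peaks were narrower in all 6 groups, for example a median of 564 bp against 1338 bp for Wdr5.

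ING1 was compared between myoblasts and myotubes, the comparison that the series design names. In the pooled lists, 5901 of 8196 ING1 myoblast peaks (72.0%, exact 95% interval 71.0 to 73.0) overlapped a myotube peak. That was 109.0 times the 0.661% at circular shifts (shift permutation p = 0.0010) and 42.1 times the 1.71% at local shifts. The share was 41.6% with unions of the replicate lists, 5599 myoblast and 3323 myotube peaks. In the other direction 62.1% of myotube peaks overlapped a myoblast peak. Among peaks found in every replicate list, the widest ING1 region of myoblasts, on chromosome 19 from 5841738 to 5845857, was 92.5% covered by a myotube peak, and the widest of myotubes, on chromosome 17 from 34253841 to 34257965, was 90.8% covered by myoblast peaks. On chromosome 13 from 30076396 to 30078567, the fifth named myotube region, 50.9% was covered by ING1 in myoblasts, and Menin covered only 29.0% of it.

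The ING1 sites shared by both states were the ones with most other factors. Sin3A in myotubes lay at 89.6% of myoblast ING1 peaks that were kept and at 41.5% of those found in myoblasts alone (odds ratio 12.1, 8.98 within classes of width). LSD1 in myoblasts lay at 44.1% of the kept and 15.2% of the myoblast-only peaks, Wdr5 at 91.2% and 65.3%, Menin at 92.5% and 75.9%, and MLL1 at 41.0% and 29.9%. The first 4 of these contrasts had the same direction on all 20 chromosomes and that of MLL1 on 18 (exact binomial adjusted p = 2.7e-06 and 0.000537). MLL3 lay at 19.3% and 17.3%, higher on 13 of 20 chromosomes (exact adjusted p = 0.283). Within classes of width the odds ratio went from 1.63 to 1.23 for MLL1 and from 1.15 to 0.942 for MLL3. The counts of chromosomes were not matched on width. ING1 peaks found in myotubes alone were poorer in the same way, with Sin3A at 63.3% against 89.8% of shared peaks and LSD1 of myotubes at 22.9% against 46.4%, both on all 20 chromosomes. Peaks of 1 state were narrower, with medians of 562 against 813 bp in myoblasts and 571 against 794 bp in myotubes. The contrasts were not repeated with peaks found in replicate lists. They therefore cannot separate binding in 1 state from less well supported peaks.

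Replicate lists gave no firm difference in ING1 between the states. ING1 had 2978 ± 3606 peaks per list in myoblasts (SD, n = 2) and 1597 ± 1285 in myotubes (SD, n = 3; exact permutation p = 0.6), a myotube minus myoblast difference of −1381. Menin covered 91.5% ± 0.930 of the peaks of the myoblast lists (SD, n = 2) and 85.3% ± 7.94 of those of the myotube lists (SD, n = 3), MLL1 43.8% ± 3.22 and 31.5% ± 8.02, and Sin3A 88.5% ± 2.77 and 92.6% ± 1.78. Each of these 3 differences reached 0.2, the smallest p that the exact permutation test allows here (adjusted p = 0.6 over 9 measures). In a test chosen after the data were seen, pairs of ING1 replicate lists shared 69.3% of the shorter list on average within a state and 57.7% between states; no other of the 10 arrangements gave so large a gap (one-sided exact permutation p = 0.1, the smallest possible). The gap rested on ING1 myoblast replicate 1: without it the averages were 65.9% within and 72.6% between states. With the widest 2163 peaks of each of the 3 longest lists, the pair from myotubes shared 55.2%, and the myoblast list shared 37.8% and 39.5% with them. The shared part of the union lists, 41.6%, moved to 28.6% without ING1 myotube replicate 2, 32.5% without ING1 myotube replicate 1 and 67.5% without ING1 myoblast replicate 2. Of the 338 myoblast peaks found in every replicate list, 6.21% met one of the 78 such myotube peaks, which are too few to meet most of them.

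LSD1 was also compared between the states. Of its 4442 myoblast peaks, 2002 (45.1%, exact 95% interval 43.6 to 46.5) overlapped a myotube peak. That was 49.3 times the 0.914% at circular shifts (shift permutation p = 0.0010) and 19.7 times the 2.29% at local shifts. Of the 16504 myotube peaks, 14611 were not listed in myoblasts and 1893 (11.5%) were. The widest LSD1 peaks of myotubes were among the new ones: the domains on chromosome 15 from 76000658 to 76020456 and from 27906686 to 27920295, and on chromosome 18 from 32564931 to 32577639, held no LSD1 peak and no MLL1 peak in myoblasts. With the myotube list shortened to its widest 4442 peaks, 17.3% of the myoblast peaks were shared. Each state had 1 list, so the difference cannot be set against a spread between replicates.

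LSD1 sites kept from myoblasts lay at ING1 and Sin3A peaks in myotubes, and new ones mostly did not. ING1 in myotubes lay at 90.2% of the kept and 13.0% of the new LSD1 peaks (odds ratio 61.6, 59.5 within classes of width), Sin3A at 94.7% and 16.2%, and Wdr5 of myoblasts at 92.0% and 20.6%. Menin of myoblasts lay at 94.9% of the kept and 36.6% of the new peaks and MLL1 at 42.6% and 6.89%. These contrasts held on all 20 chromosomes (exact binomial adjusted p = 2.7e-06). MLL3 went the other way, at 21.6% of the kept and 26.0% of the new peaks (odds ratio 0.784, lower on 16 of 20 chromosomes, exact adjusted p = 0.0144). Among LSD1 peaks of myoblasts, those with an ING1 peak in myoblasts were kept in 49.9% of cases and those without in 32.8% (odds ratio 2.04, the same direction on all 20 chromosomes). Myoblast LSD1 peaks that were not kept also lay mostly at these factors. ING1 of myotubes lay at 72.5% of them against 88.4% of the kept ones, and Sin3A at 77.6% against 93.6%. Wdr5 lay at 86.4% against 91.8%, and Menin at 91.8% against 94.4%.

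**Figure D2:**
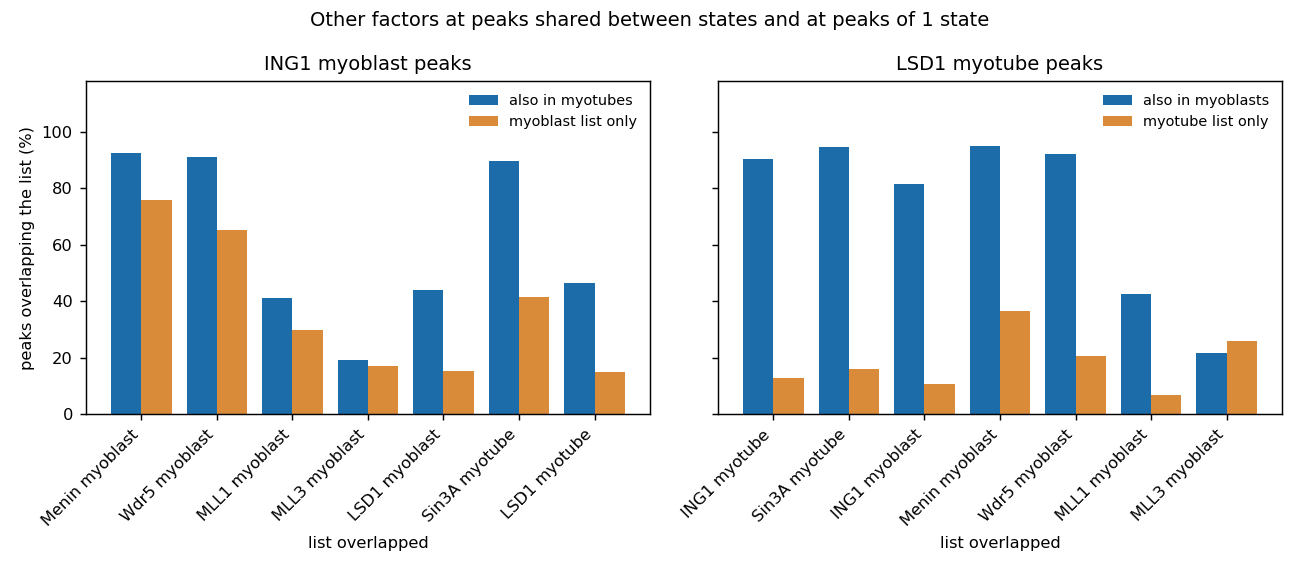
Share of peaks (y axis, %) that overlap each other list (x axis), for ING1 myoblast peaks also found in myotubes or not (left) and for LSD1 myotube peaks also found in myoblasts or not (right). Bars are shares of pooled or single lists without error bars; new LSD1 peaks fall from 90.2% to 13.0% for ING1 and rise from 21.6% to 26.0% for MLL3.

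The myoblast lists were compared in pairs to see which factors occupied the same places. ING1 peaks lay largely inside the Menin and Wdr5 lists: 87.8% overlapped Menin, 83.9% Wdr5 and 77.0% both, and 434 of 8196 (5.30%) overlapped neither. Across the ING1 myoblast replicate lists the share at Menin was 91.5% ± 0.930 and at Wdr5 91.5% ± 1.81 (SD, n = 2). MLL1 lay at 37.9% of ING1 peaks, while 74.0% of MLL1 peaks overlapped Menin and 59.1% overlapped Wdr5. LSD1 peaks of myoblasts lay largely in the longer lists, with 93.0% at Menin, 88.9% at Wdr5, 71.7% at ING1 and 37.6% at MLL1 peaks, and 43 of 4442 overlapped none of these 4. Wdr5 and Menin, the longest lists after MLL3, shared 29.2% of Wdr5 peaks, and 63.7% with unions of replicate lists.

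All 15 myoblast pairs exceeded every circular shift (permutation by shifts, adjusted p = 0.0010), from 154.4 times the shifted share for LSD1 at ING1 to 1.27 times for MLL1 at MLL3. Against local shifts these 2 ratios were 59.1 and 0.877. Several shares moved when 1 library was left out: ING1 peaks at MLL1 fell from 26.9% with unions of replicate lists to 5.18% without MLL1 replicate 1. LSD1 at ING1 went from 56.3% to 4.82% without ING1 myoblast replicate 2, and LSD1 at MLL1 from 23.1% to 3.13% and MLL1 at Wdr5 from 48.8% to 76.8% without MLL1 replicate 1. The falls left only 466 MLL1 or 428 ING1 peaks to be met, which limits these shares. Ratios to circular shifts rose instead, from 105.9 to 192.7 for ING1 at MLL1. They rose from 190.4 to 279.7 for LSD1 at ING1 and from 108.1 to 146.3 for LSD1 at MLL1. With every list shortened to its 4442 widest peaks, ING1 at Menin was 52.0% and LSD1 at Menin 47.9%.

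**Figure D3:**
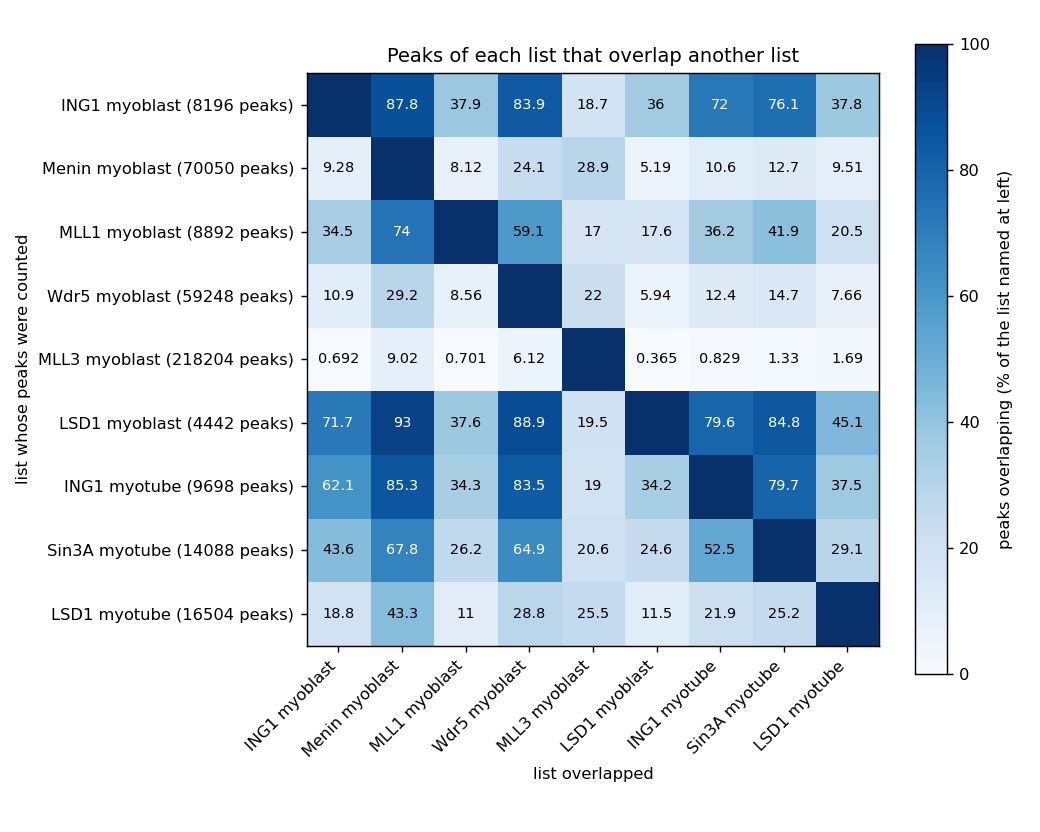
Percentage of the peaks of each list (rows, with the number of nuclear peaks) that overlap each other list (columns) by at least 1 bp; darker cells are higher. The LSD1 myoblast row reaches 93.0% at Menin, and no list exceeds 28.9% at MLL3.

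MLL3 stood apart from the other myoblast factors. Its list overlapped 18.7% of ING1 peaks, 17.0% of MLL1 peaks, 19.5% of LSD1 peaks, 22.0% of Wdr5 peaks and 28.9% of Menin peaks, against 11.4% to 14.9% at circular shifts (ratios 1.27 to 1.94, and 2.90 to 4.98 with every list shortened to its 4442 widest peaks). Set against shifts within 20 to 200 kb, a comparison chosen after these values were seen, MLL3 was less frequent at ING1 peaks than around them in myoblasts (18.7% against 23.3%, ratio 0.802) and in myotubes (19.02% against 23.2%, ratio 0.821). It was also less frequent at MLL1 (ratio 0.877) and Sin3A peaks (0.898), and more frequent at Menin (1.29), Wdr5 (1.12) and the LSD1 peaks of myotubes (1.099; shift permutation, adjusted p = 0.0011 for each of these 7). At LSD1 peaks of myoblasts the ratio was 0.997 (shift permutation, adjusted p = 0.483), but 1.16 with overlap of 50% of the shorter peak and 1.11 with the wider 50% of each list (shift permutation p = 0.00498 and 0.0299). With unions of the replicate lists in place of the pooled lists the Menin ratio was 1.102, and it turned to 0.963 without Menin replicate 1. The Wdr5 excess already turned to 0.924 with the union, and was 0.878, 0.943 and 0.919 without Wdr5 replicates 1, 2 and 3. With the wider 50% of each list the deficit was no longer past the threshold at ING1 peaks of myoblasts (ratio 0.950, shift permutation p = 0.0846) and myotubes (0.974, p = 0.234) or at Sin3A peaks (0.967, p = 0.0896). With peaks found in every replicate list the ratio was 1.003 for ING1 in myotubes (shift permutation p = 0.587) and 0.908 for Sin3A (p = 0.134). In that setting the excess turned to 0.945 for Menin (shift permutation p = 0.00995) and 0.975 for Wdr5 (p = 0.159). The deficit remained for ING1 in myoblasts (0.763) and MLL1 (0.666). The MLL1 ratio against circular shifts turned from 1.15 with unions to 0.749 without MLL1 replicate 1.

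With all peaks as listed, MLL3 peaks covered 10.6% of ING1 peak centres in myoblasts, 15.6% of positions 10 kb away and 11.5% of positions 500 kb away. At LSD1 peaks of myotubes coverage was higher at the centre than at 10 kb, with 21.2% at the centre, 16.8% at 10 kb and 12.7% at 500 kb. Menin had 19.2%, 15.3% and 10.5% at these distances. The widest MLL3 regions, on chromosome 9 from 120843629 to 120865438 and on chromosome 2 from 27764966 to 27784046, held no Wdr5, MLL1, Sin3A or myoblast LSD1 peak, and LSD1 of myotubes covered 56.7% and 63.5% of them. In the other 3 named MLL3 regions LSD1 of myotubes covered 22.7%, 22.6% and 13.1%, and each held Sin3A or MLL1 peaks. These lay on chromosome 8 from 86097093 to 86114955, on chromosome 15 from 66734361 to 66750489 and on chromosome 8 from 87246074 to 87261568.

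**Figure D4:**
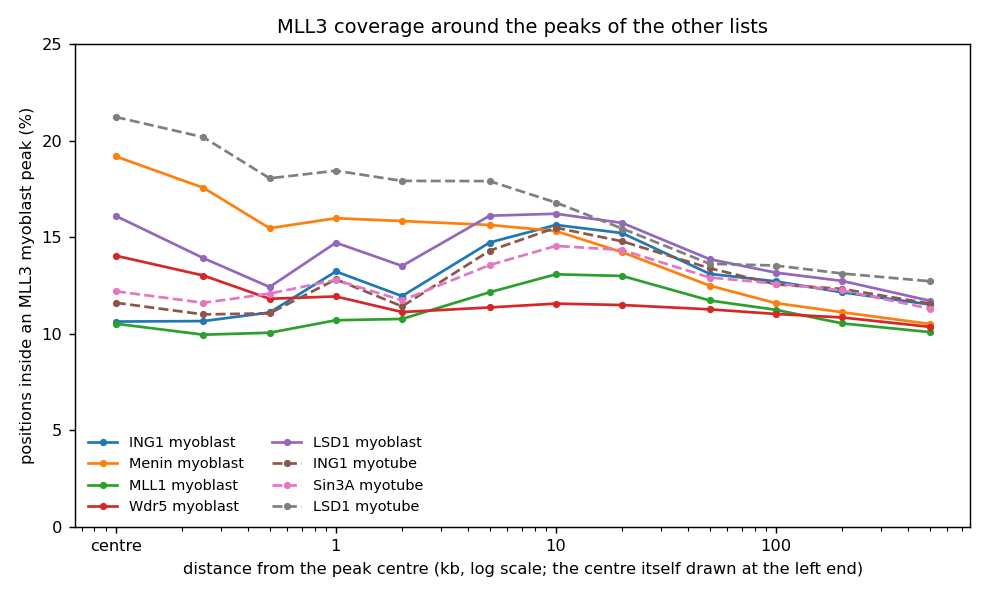
Percentage of positions inside an MLL3 myoblast peak (y axis) with distance from the peak centres of the 8 other lists (x axis, kb, log scale, centre at the left end; solid lines myoblast lists, dashed myotube lists). ING1 in myoblasts rises from 10.6% at the centre to 15.6% at 10 kb, and LSD1 in myotubes falls from 21.2% to 16.8%.

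In myotubes ING1 and Sin3A shared most of their sites. Of the ING1 peaks, 79.7% overlapped a Sin3A peak, 82.7 times the share at circular shifts and 32.5 times that at local shifts. In turn, 52.5% of Sin3A peaks overlapped ING1. In the 3 ING1 myotube replicate lists the share at Sin3A was 92.6% ± 1.78 (SD, n = 3). LSD1 lay at 37.5% of ING1 peaks (33.9 times the share at circular shifts, 13.6 times that at local shifts). LSD1 overlapped 29.1% of Sin3A peaks (25.7 and 10.4 times). ING1 peaks with LSD1 nearly always had Sin3A as well: 3409 peaks (35.2%) had both, 4324 (44.6%) Sin3A alone, 225 (2.32%) LSD1 alone and 1740 (17.9%) neither. Of the LSD1 peaks, 12098 (73.3%) met neither ING1 nor Sin3A. The 3 pairs exceeded every shift (permutation by shifts, adjusted p = 0.0010), and the ING1 share at Sin3A fell from 87.8% with unions of replicate lists to 10.5% without Sin3A replicate 1. Only the 430 peaks of Sin3A replicate 2 were then left to be met, which limits that share. The ratio to circular shifts rose from 144.4 to 454.9.

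The named regions, the widest peaks found in every replicate list, were compared across the 9 lists. The widest Menin domain, on chromosome 15 from 102772057 to 102820089 (48033 bp), was 87.9% covered by MLL1 and 86.6% by Wdr5, and held 16 ING1 peaks in myoblasts and 10 in myotubes. The next, on chromosome 6 from 52158998 to 52192217, was 86.0% covered by MLL1 and 76.4% by Wdr5, with LSD1 of myotubes on 3.30% and MLL3 on 3.23% of it. The next 2, on chromosome 15 from 85482648 to 85513153 and on chromosome 12 from 74133188 to 74156175, were covered by MLL1 over 84.9% and 66.5%. The fifth, on chromosome 1 from 148336622 to 148357047, had MLL1 on 71.7% but Wdr5 on 22.5%, and no ING1 peak in myoblasts. The widest MLL1 peak (chromosome 15, 102804296 to 102814818), the second (chromosome 6, 52169376 to 52178204) and one further MLL1 peak (chromosome 12, 74139472 to 74148090) lay inside these domains. The third MLL1 peak, on chromosome 16 from 43500797 to 43509607, had Menin and Wdr5 but no ING1, LSD1 or Sin3A peak.

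Other named regions were crowded with factors. The widest Wdr5 domain, on chromosome 19 from 5835354 to 5849634, contained the widest ING1 myoblast peak among those found in both replicate lists, and met all 9 lists. A region on chromosome 8 from 86724792 to 86728052 was fully covered by ING1, Menin, Wdr5 and Sin3A peaks, and 91.2% covered by LSD1 in myotubes. The widest Sin3A region, on chromosome 10 from 79610281 to 79615602, was 66.0% covered by ING1 in myotubes and held no LSD1 peak in myoblasts and 4 in myotubes. The widest LSD1 peak of myoblasts, on chromosome 2 from 13496618 to 13498324, was fully covered by Menin, Wdr5 and MLL3 peaks and met all 9 lists.

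**Figure D5:**
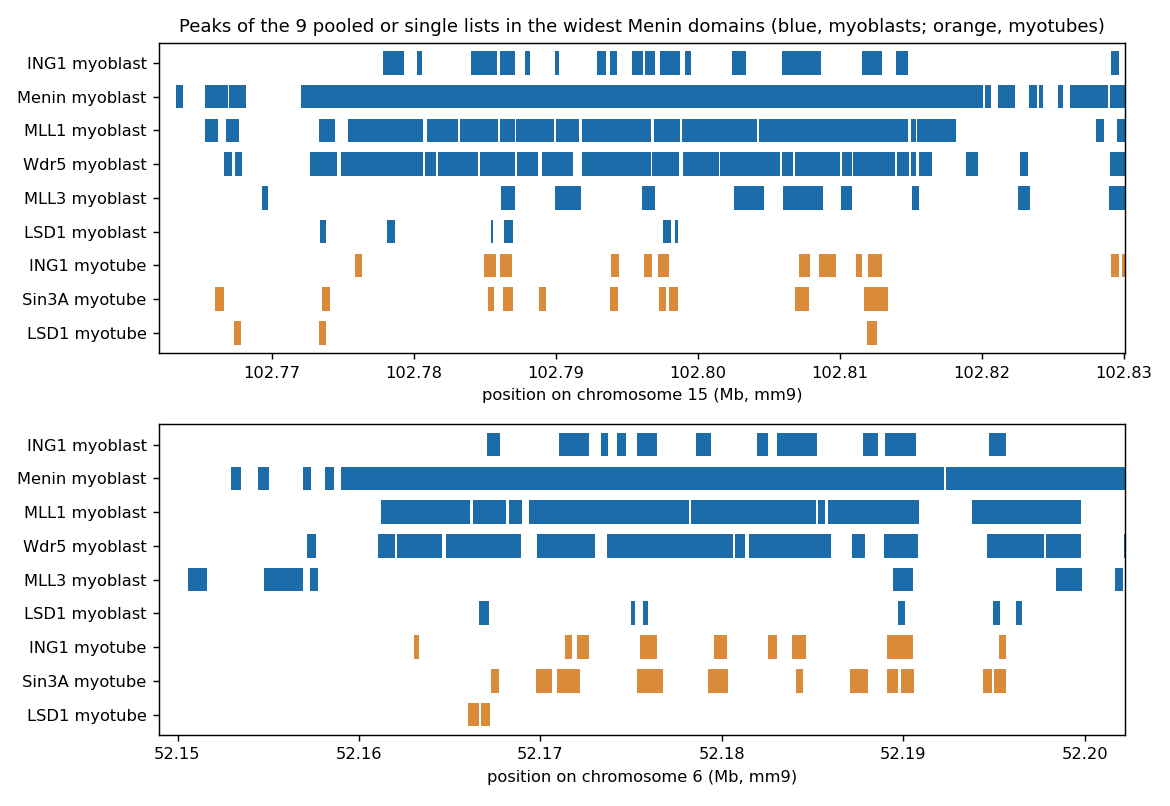
Peaks of the 9 lists (one line each; blue, myoblasts; orange, myotubes) along mm9 positions in Mb (x axis) of the 2 widest Menin domains, on chromosomes 15 and 6. MLL1 and Wdr5 blocks fill most of each domain (87.9% and 86.6% on chromosome 15), and ING1, LSD1 and Sin3A appear as short separate peaks.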

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

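The test of the difference between ING1 and LSD1, and the tests of chromosomes 8 and 15 and of random positions, were chosen after the overlaps were seen. In the lists as deposited, 72.0% of the myoblast sites of ING1 and 45.1% of those of LSD1 were listed in myotubes, a difference of 26.9 percentage points (odds ratio 3.13) that had the same direction on all 20 chromosomes (exact binomial p = 1.9e-06, the smallest that 20 chromosomes allow in this two-sided test). The ranking held with the wider 50% of each list (62.9% for ING1 and 35.7% for LSD1), overlap of 50% of the shorter peak (68.3% and 40.4%) and peaks within 500 bp (77.1% and 52.5%). The order was the same with both lists of each factor cut to their widest peaks at equal length (66.5% and 17.3%). Those lists held 8196 peaks for ING1 and 4442 for LSD1, so the factors were not matched in length. The cut also took far more of the LSD1 myotube list, from 16504 peaks, than of the ING1 one, from 9698. This setting therefore cannot support the ranking. The ranking turned with unions of the ING1 replicate lists (41.6%). ING1 had 28.6% without ING1 myotube replicate 2, 32.5% without ING1 myotube replicate 1, 41.3% without ING1 myotube replicate 3, 41.7% without ING1 myoblast replicate 1 and 67.5% without ING1 myoblast replicate 2. These turns cannot decide the ranking, because list length limits the ING1 share, though to differing degrees. The unions held 5599 myoblast and 3323 myotube peaks, and the latter fell to 2205 and 2540 without myotube replicates 2 and 1. The full union of 3323 could still have met more than 45.1% of the 5599, so length alone did not force that turn. The LSD1 myotube list, with 16504 peaks, was instead longer than its myoblast list of 4442. LSD1 had no replicate lists, and chromosomes do not replace them, so the data do not settle which factor kept more sites.

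LSD1 was also listed at 14611 myotube sites that its myoblast list lacked. If the shorter myoblast list had only missed weaker peaks, the strongest myotube peaks should mostly lie in it. Width stood in for strength, and 15.0% of the widest 4442 myotube peaks lay in it. That share did not rise steadily with width, from 10.7% up to 1 kb and 15.5% for 1 to 2 kb to 8.93% for 5 to 10 kb. Width may thus not track strength here, and the 15.0% cannot decide whether weaker peaks were missed. Apart from that, only 45.1% of myoblast peaks were found in the longer list. Chromosomes 8 and 15, where this list is richest relative to their protein-coding genes, held 17.4% of the new peaks, and 88.1% of myotube peaks on the other chromosomes were new. The Menin list met 36.6% of the new peaks, 3.21 times the share at local shifts (shift permutation p = 0.0010). That argues against random positions for the new peaks as a whole. It cannot exclude background among the new peaks that met no Menin peak, or background that gathers where other lists have peaks. A change of LSD1 targets with differentiation may remain as an explanation, untested, and so does any other difference between the 2 unreplicated experiments.

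Peaks on the mitochondrial genome, outside every comparison above, exceeded 3, the number that a count of 0 allows, in 6 of the 9 pooled or single lists: 13 for ING1 in myoblasts, 13 for Menin, 15 for MLL1, 14 for Wdr5, 11 for ING1 in myotubes and 7 for LSD1 in myotubes. The pooled Sin3A list held 2, but its replicate lists held 9 and 15.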

How the results depend on the processing

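Local shifts and peaks present in every replicate list were alternatives chosen after the data were seen, as were all tests of MLL3 against local shifts. The 15 pooled overlaps without MLL3 kept their direction and side of the threshold in all 125 alternatives (lowest ratio 3.45), as did the 10 pairs of replicate lists in 20. Of 32 alternatives for the 5 pooled overlaps with MLL3, 27 agreed. The ratio fell below 1 with local shifts for ING1 (0.802), MLL1 (0.876) and LSD1 (0.994), and for MLL1 peaks in every replicate list (0.926); without 1 replicate the MLL1 ratio ran from 0.749 to 1.15. Against local shifts, 36 of 50 alternatives agreed. With the wider 50% of each list the ratio was 0.950 for ING1 in myoblasts, 0.974 for ING1 in myotubes and 0.967 for Sin3A, no longer past the threshold, and 1.11 for LSD1 in myoblasts, which was 1.16 with overlap of 50% of the shorter peak. With peaks in every replicate list it was 0.945 for Menin, 0.975 for Wdr5, 1.003 for ING1 in myotubes and 0.908 for Sin3A. Without 1 replicate it ran from 0.963 to 1.09 for Menin and from 0.878 to 0.943 for Wdr5, which was 0.924 with the union of its replicate lists. The cause was not tested in these cases. The myotube minus myoblast difference in ING1 peaks per list, −1381, was −645.5 with the replicate number as a block (exact p = 1, with 0.5 the smallest that 2 pairs allow), the same as without ING1 myotube replicate 3, which the block leaves out, and ran from −3931 to 1169 without 1 replicate, reversed without ING1 myoblast replicate 2. The share of ING1 replicate pairs within minus between states, 11.6 percentage points, ran from −6.68 to 23.1 without 1 list. The share of sites kept, ING1 minus LSD1, was −3.49 points with unions, −38.9 with peaks in every replicate list, where ING1 had 338 myoblast and 78 myotube peaks, and −16.4 to 22.5 without 1 replicate, reversed in 6 of 11 alternatives. In each reversal the ING1 myotube list was shorter than the myoblast list, which limits the ING1 share but did not by itself force the reversal with unions. Promoter windows, peak location relative to genes and gene lists with their backgrounds were not run, since no annotation of build mm9 was used here; lists without replicates have no replicate alternative. Sequencing depth is unknown, so list lengths set the shares that long lists can reach.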

Other observations

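The tests of width classes, of Menin and MLL3 domains and of reads recovered at ING1, MLL1 and Sin3A sites were chosen after the data were seen. The broadest Menin peaks were covered most by MLL1 and Wdr5. MLL1 covered 1.37% of the base pairs of Menin peaks up to 1 kb, 4.91% for 1 to 2 kb, 13.9% for 2 to 5 kb, 26.0% for 5 to 10 kb and 49.4% of the 48 Menin domains over 10 kb, 171.8 times the coverage of shifted domains (shift permutation p = 0.0010). Wdr5 went from 9.86% to 47.9% over the same classes, with 39.8% for 2 to 5 kb and 36.7% for 5 to 10 kb. Its coverage of the domains was 20.8 times that of shifted domains. That was less than for ING1 in myoblasts (65.2), LSD1 in myoblasts (48.0), ING1 in myotubes (42.4) and Sin3A (29.1). It was more than for LSD1 in myotubes (20.6) and MLL3 (1.39). ING1 in myoblasts levelled off between 18.3% and 19.4% in the last 3 classes, and MLL3 went from 19.2% to 11.9%. These 48 domains lay in both Menin replicate lists, 47 met MLL1, and 15 met all 9 lists. Of all pooled Menin peaks, 71.1% met no replicate peak, and these were narrower (median 567 bp against 1405 bp). The rise with width thus cannot be told apart from better replicate support of wide peaks.

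Broad MLL3 peaks of myoblasts were covered by LSD1 of myotubes and by Menin. LSD1 of myotubes covered 0.470% of the base pairs of MLL3 peaks up to 1 kb, 5.62% for 2 to 5 kb, 16.6% for 5 to 10 kb and 26.6% of the 29 MLL3 domains over 10 kb, 37.2 times the coverage of shifted domains (shift permutation, adjusted p = 0.0040), and met 75.9% of these domains against 6.62% of shifted ones. Menin covered 4.85% of the narrowest class and 24.2% of the 29 domains, 7.25 times the shifted coverage (shift permutation, adjusted p = 0.0040). Sin3A covered 1.96% of them, 3.30 times the shifted coverage (shift permutation, adjusted p = 0.0107). Coverage by the other 5 lists did not pass the threshold (shift permutation, adjusted p of 0.0859 or more), among them Wdr5 with 3.01% against 2.43% and LSD1 of myoblasts with 0.280%. By the share of domains met, ING1 of myoblasts did pass, with 17.2% against 4.41% of shifted domains (shift permutation, adjusted p = 0.0140), and the rest of these 5 did not. MLL3 and LSD1 of myotubes had 1 list each, from different states, and the inputs were not analysed. Background common to these 2 lists was therefore not tested.

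With all peaks as listed, MLL3 peaks were fewer at ING1, MLL1 and Sin3A sites than nearby. The test of a general failure to recover reads there could not decide, but the Menin and Wdr5 lists did have peaks at most of these sites. They met 64.9% or more of the ING1 and Sin3A peaks and 59.1% or more of the MLL1 peaks. Their shares were 7.70 and 11.3 times those at local shifts for ING1 myoblast peaks, and 7.36 and 9.33 times for MLL1 peaks. The test could not decide because Wdr5 at MLL1 peaks, with 59.1%, was under the bound of 60%. Sites that are themselves called peaks were also chosen for having reads. Dilution by weak MLL3 peaks could not be excluded: with the wider 50% of the MLL3 list the ratio at ING1 myoblast peaks was 0.936 (14.8% against 15.8% at local shifts, shift permutation p = 0.0080), between the bounds set beforehand, so the dip shrank without turning. A loss of reads at these sites in the MLL3 library alone also stays open. No biological explanation was tested.

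Chromosome 15 was rich in peaks in all 9 lists, and more copies of it in these cells could let weak peaks pass. The share of chromosome 15 was higher among pooled peaks found in no replicate list in 3 of 6 groups. That count met the bound set beforehand against the explanation, but the bound ignored size: for Sin3A the shares were 11.4% and 5.14% and for Wdr5 9.93% and 6.57% (Fisher exact adjusted p = 7.8e-40 and 3.3e-27), and the other 4 groups differed little (adjusted p of 0.210 or more). The explanation therefore stays open for Sin3A and Wdr5. It is not excluded for the other 4 groups either, because more copies could also raise the peaks found in replicate lists and leave the shares alike. The inputs were not analysed, and no biological explanation was tested.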
